A study of Mus musculus with 32 samples.

How the data were processed

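Mouse amygdala was injected with 100 mM 4sU in DMSO or with DMSO 24 h before RNA extraction with Trizol, and the RNA was alkylated, per the labels' protocols. Libraries were made with the VAHTS Universal V8 kit, and the amygdala of both sides was taken, per the labels' protocols. The labels place 26 amygdala libraries in 6 groups of state (baseline, acute stress, chronic stress) and injection, and 6 auditory cortex libraries in a group with and a group without 4sU. All sample columns were matched to their samples by the names in the labels.

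The authors deposited 2 tables of amygdala exon counts per gene symbol, one with baseline and acute and one with baseline and chronic libraries, as whole numbers with no normalization. The submitters' processing notes name cutadapt 3.1, HISAT2 2.1.0, SAMtools 1.9 and featureCounts 2.0.1, without their roles or order, and the mm10 genome build. The strand setting and the treatment of reads with several matches are not given in the sources used here, so counts of overlapping, antisense and paralogous genes are uncertain. Both tables held 25239 genes, and their 9 shared baseline columns differed in 0 values, so they were joined. The cortex table holds deposited counts per Ensembl transcript. Of its 142552 transcripts 89381, with 79.6% of the counts, were matched to a gene symbol. The match was by position, as the amygdala gene whose exons overlapped at least 50% of the transcript's bases on the same strand.

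For each amygdala library the authors also deposited a table of conversion counts per RefSeq 3′ UTR interval, made with slamdunk 0.4.3, per the file headers. It gives covered T positions, T-to-C conversions, reads and reads with a conversion. The conversion rate in these tables is a fraction, conversions over covered T positions, per the file headers, and their CPM column scales reads to the library's total, per the file headers. The base quality threshold, variant filter and multiple-match setting are not given in the sources used here. Of 23996 intervals 23894 carried a symbol. For each of 19262 genes the interval with the most covered T positions was used, which kept 87.5% of them. Libraries had 2.18e+08 to 3.48e+08 covered T positions, so an overall rate rests on far more conversions than the rate of a gene near the minimum of 2000 positions, which rests on a few at most.

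Counts were tested with edgeR 4.0.16 in R 4.3.3. TMM scaling, filterByExpr and robust quasi-likelihood fits were used with 1 coefficient per group. The 4 groups of a table shared a fit, and chronic against acute stress was tested in a fit of all 6. Stress effects were tested in each injection arm, as their average and as their difference, and 4sU was compared with DMSO in each state. Genes with an adjusted p under 0.05 are said to be higher, lower, to have risen or to have fallen. The per-gene conversion rate was tested with edgeR on conversions with the log of covered T positions as offset, in genes with a mean of at least 2000 such positions and some in every library. The tests of stress also rescaled libraries to a common overall rate. Overall rates were compared with exact permutation tests (SciPy 1.17.1), two-sided. Gene lists were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01, adjusted over the lists of a comparison), beside a count of members and a count adjusted over the list alone. Across 13 comparisons camera made 93 calls with the preset correlation and 8 with an estimated one, of 338. For conversion, a list's median excess was ranked among 10000 random lists. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. The edgeR tests were first tested on simulated data with 200 changed genes, for 8 of the 18 comparisons: for the acute average 76.1% of genes changed 1.5-fold and 91% changed 2-fold were recovered, for chronic against baseline DMSO mice 53.7% and 79.1%, and for the cortex 0% and 19.4%. For conversion at baseline, 3% of genes changed 2-fold and 50% changed 4-fold were recovered. The spread simulated for conversion was set and not estimated from the libraries.

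Groups, tests, 28 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes are, per stress comparison, the 8 largest rises and 8 largest falls past the threshold with at least 1 CPM and the same direction in both arms, leaving out symbols of predicted genes. To these come 12 fixed genes (Fos, Arc, Npas4, Egr1, Nr4a1, Bdnf, Fkbp5, Sgk1, Tsc22d3, Crh, Nr3c1 and Gfap) and up to 4 members of each list with the smallest p. For 4sU against DMSO and for conversion under stress they are the 8 largest rises and falls, and for labelling the 10 called genes with the largest excess at baseline. Genes outside this rule that the text names, such as Slc17a7, Ttr, Mbp and the cortex transcripts, were chosen after their values were seen. Results for some genes are not reported here.

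Replicates of a group differed by more than counting noise: in the closest of 45 amygdala pairs the chi-square per degree of freedom was 3.55, and in the closest of 6 cortex pairs 7.05. Comparisons that share baseline libraries were set against 20 simulations of unchanged groups. Alternatives were DESeq2 1.42.0, another normalization, no filter on low counts, 3′ UTR reads in place of exon counts, all 6 groups or only 2 in a fit, the replicate number as a block, other coverage minimums, limma on rates (added 0.1 percentage points), reads with a conversion, no rescaling and leaving out each library in turn. A fit with a term for the division of libraries, fits without 5 libraries and cortex counts summed per symbol were added after the data were seen. No genome sequence was used here, so GC content was not analysed here.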

Results

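Total RNA from mouse amygdala was sequenced after metabolic labelling in the living animal. The uridine analogue 4-thiouridine (4sU), which is built into newly made RNA and read after alkylation as a T-to-C conversion, or its solvent DMSO was injected into the amygdala 24 h before the tissue was taken. Mice were at baseline, after acute stress or after chronic stress, and each state had 4sU and DMSO mice. There were 5 baseline 4sU, 4 baseline DMSO, 5 acute 4sU, 5 acute DMSO, 4 chronic 4sU and 3 chronic DMSO libraries. A further 3 libraries with 4sU and 3 without came from auditory cortex. Amygdala libraries held 16150316 to 21228741 exon counts each, and cortex libraries 9702616 to 13539231 transcript counts. The labels call replicates separate samples without saying more of the animals, so p-values measure the spread between these samples. Adjusted p-values for genes come from edgeR's quasi-likelihood test (two-sided, Benjamini-Hochberg adjustment), and log2 fold changes are given ± SE.

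Acute stress was compared with baseline to ask how the amygdala transcriptome answers a short stressor. Transcripts that glucocorticoid hormones induce rose in both injection arms. Sgk1, a glucocorticoid-induced kinase (chromosome 10, 21882184 to 21999902 in mm10), went from 98.5 ± 15 to 292 ± 7.4 CPM (mean ± SD of library-size normalised counts) in 4sU mice. In DMSO mice it went from 144 ± 101 to 493 ± 106 CPM, and the mean log2 fold change was 1.68 ± 0.20 (adjusted p = 6.0e-05). Baseline DMSO library 4 had 289 CPM, while the others of its group had 69.7 to 134 CPM. Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28398753 to 28486149), rose by 0.84 ± 0.11 (adjusted p = 0.00015). It went from 62.9 ± 5.8 to 108 ± 6.2 CPM in 4sU mice and from 55.7 ± 21 to 102 ± 8.2 CPM in DMSO mice. Tsc22d3, which encodes the anti-inflammatory leucine zipper GILZ (chromosome X, 140539529 to 140600522), rose by 1.12 ± 0.11 (adjusted p = 4.7e-06). Averaged over the 2 arms, 236 genes were higher and 146 lower of 15995 tested.

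**Figure D1:**
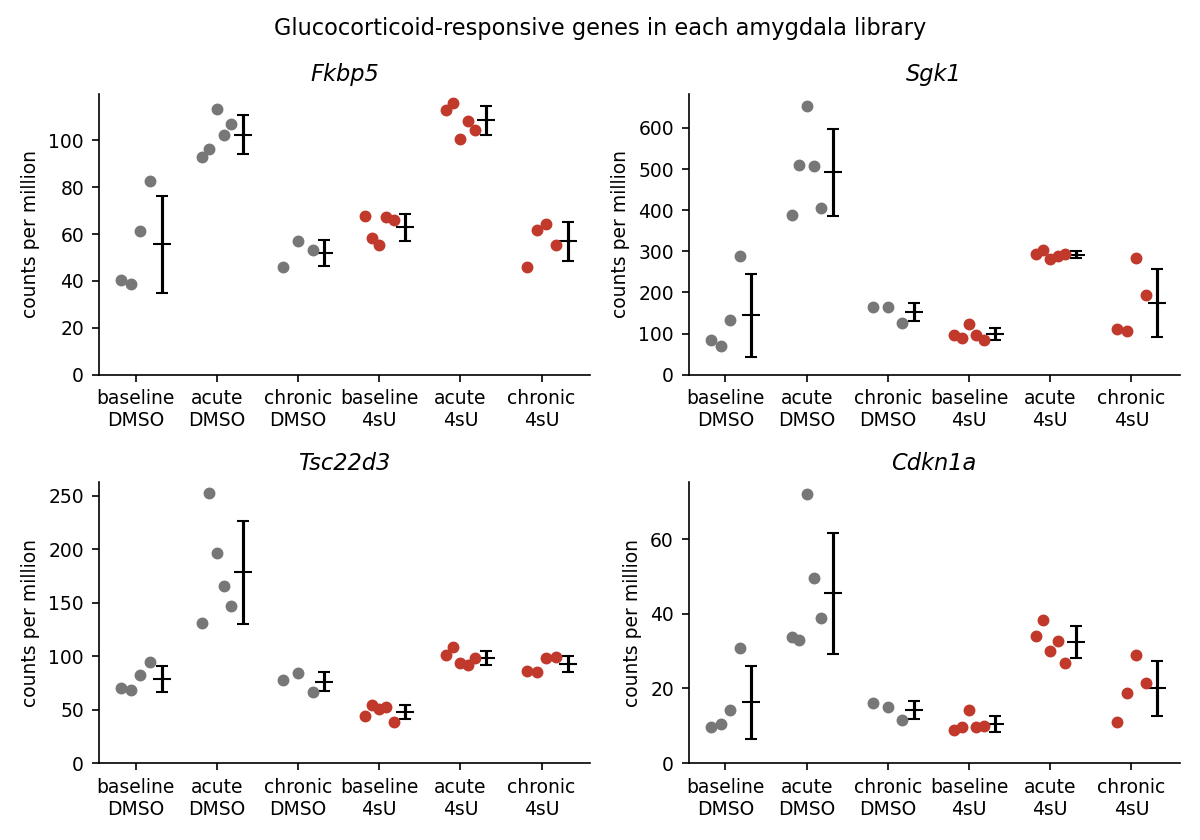
Normalised expression (CPM) of Fkbp5, Sgk1, Tsc22d3 and Cdkn1a in each amygdala library, with points for libraries, black dashes and bars for the group mean ± SD, grey for DMSO and red for 4sU. Mean Sgk1 was 292 CPM in acute 4sU and 493 CPM in acute DMSO libraries, against 98.5 and 144 CPM at baseline.

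Of the 26 measured genes in the list of glucocorticoid-responsive genes, 21 rose and 0 fell (22 and 0 adjusted over the list alone), 25 had a log2 fold change above 0, and the median was 0.78. The list stood apart from all other genes (camera, adjusted p = 7.7e-73; adjusted p = 0.00034 with an estimated correlation). The DNA-damage and stress-induced mTOR inhibitor Ddit4 rose by 1.31 ± 0.12 and the NF-kappaB inhibitor Nfkbia by 1.20 ± 0.11 (adjusted p = 4.7e-06 for each). In 4sU mice alone 11 of the 26 rose, and in DMSO mice 15, with 0 falling in either arm. Other large rises were those of the arrestin-domain gene Arrdc2 (1.82 ± 0.18, 17.2 to 64.3 CPM in 4sU mice) and of Plekhf1 (1.42 ± 0.13, adjusted p = 4.7e-06 for each). They were joined by adenosine deaminase Ada (2.01 ± 0.21, adjusted p = 1.2e-05), Tmem252 (1.92 ± 0.23, adjusted p = 6.0e-05) and the cell cycle inhibitor Cdkn1a (1.56 ± 0.20, adjusted p = 0.00013). The integrin Itgad rose by 1.44 ± 0.24 (adjusted p = 0.0015). Ada was at a low level throughout, 1.17 CPM in baseline and 4.10 CPM in acute 4sU mice. Pmch, the precursor of melanin-concentrating hormone, had the largest mean rise, 2.94 ± 0.74 (adjusted p = 0.042), but it varied widely between acute DMSO libraries (5.90 ± 6.2 CPM) and lost its call in 13 of 19 fits without 1 library.

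Among genes that fell, the apoptosis-inducing ligand Tnfsf10 dropped by 1.43 ± 0.16 (adjusted p = 2.1e-05) and the muscle-type protein gene Igfn1 dropped by 1.64 ± 0.30 (adjusted p = 0.0043). The cadherin Cdh3 had a log2 fold change of -1.26 ± 0.23 (adjusted p = 0.0041), the endothelial lectin Clec14a -1.22 ± 0.19 (adjusted p = 0.0011) and the myeloid receptor Gpr84 -1.16 ± 0.23 (adjusted p = 0.0078). The homeobox gene Msx1 had -1.14 ± 0.25 (adjusted p = 0.014) and the interferon-induced GTPase Gbp4 -1.10 ± 0.28 (adjusted p = 0.040, lost in 13 of 19 fits without 1 library). Bmp3, a bone morphogenetic protein, had -1.14 ± 0.21 (adjusted p = 0.0049), with -2.25 in DMSO mice and -0.04 in 4sU mice. Endothelial genes were split, with 2 of 18 list members higher and 3 lower. The glucose transporter Slc2a1 rose by 0.59 and the lipid transporter Mfsd2a by 0.65, while the tight junction gene Cldn5 had -0.89 and the VEGF receptor gene Kdr -0.83 (adjusted p = 0.0013, 0.00066, 0.0015 and 0.00046). The list as a whole did not stand apart from other genes (adjusted p = 0.54).

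Immediate early genes, which neurons switch on within minutes of activity, did not move together. Of 30 measured, 2 rose and 3 fell (adjusted p for the list = 0.54, median log2 fold change -0.00). Npas4 and Nr4a1 were lower (-0.64 ± 0.17, adjusted p = 0.047, and -0.50 ± 0.11, adjusted p = 0.023), although Npas4 lost its call in 15 of 19 fits without 1 library. Nr4a1 lost its call without baseline DMSO library 2 (-0.48, adjusted p = 0.056), with 3′ UTR reads, with all 6 groups in a fit and with a term for sets of libraries. Fos (-0.02), Arc (-0.42) and Egr1 (-0.39) did not pass (adjusted p = 0.98, 0.18 and 0.36). Bdnf (0.15), corticotropin-releasing hormone Crh (0.07), the glucocorticoid receptor Nr3c1 (-0.19) and the astrocyte filament gene Gfap (-0.07) did not pass either (adjusted p = 0.92, 0.85, 0.28 and 0.89). Without 5 libraries low in glutamatergic markers, a choice made after the data were seen, Egr1 (-0.71) and Nr3c1 (-0.34) passed as lower and Bdnf (0.69) as higher (adjusted p = 0.014, 0.010 and 0.0089). Acute DMSO mice are represented in that fit by libraries 2 and 5 alone. None of the 31 stress hormone and neuropeptide genes or the 19 circadian clock genes passed (edgeR; adjusted p for the lists = 0.68 for each). Neuronal lists did not stand apart, with adjusted p = 0.59 for presynaptic, 0.25 for postsynaptic, 0.50 for GABAergic and 0.25 for glutamatergic genes.

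Glial genes moved too. Of 18 oligodendrocyte and myelin markers 6 rose, among them Mobp (0.48) and Mal (0.43, adjusted p = 0.010 for each). The list had adjusted p = 1.4e-12 (adjusted p = 0.25 with an estimated correlation). In DMSO mice 10 of the 18 rose with a median of 0.61, and in 4sU mice 0 passed by edgeR with a median of 0.05. Acute DMSO libraries 1, 3 and 4 had a mean log2 CPM of glutamatergic neuron markers of 2.20 to 3.16, against 4.27 to 4.67 in baseline DMSO libraries. The test of the difference between the arms called 0 of the 18 over all genes and 14 adjusted over the list alone (list adjusted p = 2.6e-15; adjusted p = 0.42 with an estimated correlation). Of 16 astrocyte markers 3 rose and 1 fell (list adjusted p = 0.00021; adjusted p = 0.25 with an estimated correlation). The gap junction gene Gjb6 (0.54) and glutamine synthetase Glul (0.37) were higher and the transcription factor Sox9 lower (-0.68), at adjusted p = 0.00054, 0.00096 and 0.00026. Of 12 oligodendrocyte precursor markers 3 rose and 1 fell (list adjusted p = 0.0012; adjusted p = 0.25 with an estimated correlation), with Olig2 at 0.41 (adjusted p = 0.0015) and Sox10 at -0.44 (adjusted p = 0.0083). Of 19 p53 targets 2 rose, Trp53inp1 by 0.64 (adjusted p = 0.0011) and Cdkn1a as above, and the list had adjusted p = 0.014 (adjusted p = 0.12 with an estimated correlation).

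Several lists leaned one way without many members passing. All 16 choroid plexus and ependymal markers had a negative log2 fold change (median -0.42, list adjusted p = 2.7e-06; adjusted p = 0.62 with an estimated correlation). Acute DMSO libraries 1, 3 and 4 had mean log2 CPM of -0.04, 3.93 and 2.66 over this list, against 4.70 to 4.99 in baseline DMSO libraries. Values were also negative for 22 of 24 interferon-stimulated genes (median -0.18, adjusted p = 0.0060) and 17 of 21 reactive glia and injury genes (median -0.17, adjusted p = 0.0040). Baseline DMSO library 4 had a mean log2 CPM of 3.458 over the interferon list, against 2.551 to 2.59 in the other 3 libraries of its group. All 54 oxidative phosphorylation genes (median 0.14, adjusted p = 1.6e-05) and all 43 ribosomal protein genes (median 0.12, adjusted p = 0.011) lay above 0 instead. Acute DMSO library 2 stood above the rest of its group in both, with a mean log2 CPM of 7.588 over oxidative phosphorylation genes (others 6.632 to 6.758) and 7.878 over ribosomal protein genes (others 6.897 to 7.088). No member of these 5 lists passed by edgeR over all genes, and these last 4 lists had adjusted p = 0.87 with an estimated correlation. Hypothalamic and thalamic markers had 1 riser, Pmch, among 18 (adjusted p = 0.0040; adjusted p = 0.27 with an estimated correlation), and meningeal markers 1 faller, Bmp6 (-0.39), among 15 (adjusted p = 0.0078; adjusted p = 0.87 with an estimated correlation).

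Markers of neurons differed between libraries. Acute DMSO libraries 1, 3 and 4, chronic 4sU library 3 and chronic DMSO library 1 had the lowest mean log2 CPM of glutamatergic neuron markers. Their values were 3.0, 2.20, 3.16, 3.81 and 2.90, each more than 1 below the median of 4.82 over 26 libraries, while chronic 4sU library 4, at 3.88, lay just inside that limit. Slc17a7, the vesicular glutamate transporter of cortical neurons, was 68.1, 15.6 and 71.1 CPM in acute DMSO libraries 1, 3 and 4. The choroid plexus gene Ttr was 2.31 CPM in acute DMSO library 1 and 5465 CPM in library 2. Without those 5 libraries, a choice made after the data were seen, 1112 genes passed in place of 382, and 308 of them were shared. Of the acute DMSO group that fit keeps libraries 2 and 5 alone. Library 2 itself stood far from its group, with 23.92% of reads in 3′ UTR intervals (others 18.45 to 19.03).

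The separate arms gave 33 higher and 10 lower genes in 4sU mice and 226 and 176 in DMSO mice. The test of the difference between the arms called 0 genes by edgeR (916 at an unadjusted p under 0.05, and 20 by DESeq2). Without the 5 libraries low in glutamatergic markers it called 313, and DMSO mice gave 2391 in place of 402. Both counts rest on acute DMSO libraries 2 and 5 alone for that group. The mean count became 249 without baseline DMSO library 1, 253 without baseline DMSO library 2 and 787 without acute DMSO library 2, and 667 genes passed by DESeq2. The count in 4sU mice became 25 without baseline 4sU library 5, 27 without library 2 and 137 in a fit of those 2 groups alone. That in DMSO mice became 143, 175 or 169 without baseline DMSO library 1, 2 or 3. It became 666, 906, 248, 200 or 716 without acute DMSO library 1 to 5, and 4 in a fit of those 2 groups alone. In the reported fit both arms share an estimate of the spread. Pairs of acute DMSO libraries differed more than pairs of acute 4sU libraries (chi-square per degree of freedom 12.3 to 113 against 5.56 to 16.7). The 402 genes called in DMSO mice thus lean on the spread of other groups.

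Chronic stress was compared with baseline for the same purpose. In DMSO mice 0 of 16096 genes passed by edgeR (913 at an unadjusted p under 0.05, 11 by DESeq2), with 4 baseline and 3 chronic libraries. Of the glucocorticoid genes that acute stress raised, Fkbp5 had a log2 fold change of -0.09, Sgk1 0.08 and Tsc22d3 -0.04 (adjusted p = 0.97, 0.99 and 0.98). Baseline DMSO library 4 had 82.7 CPM of Fkbp5 and 289 CPM of Sgk1, where the other 3 baseline DMSO libraries had 38.7 to 61.2 and 69.7 to 134 CPM. Sgk1 in chronic DMSO libraries was 127 to 165 CPM. For Sgk1, chronic stress versus baseline, expression averaged over both arms, gave 0.44 (adjusted p = 0.26), and 0.76 (adjusted p = 0.021) without that library. Reactive glia and injury genes leaned upward in these mice, 20 of 21 with a median of 0.37 and a list adjusted p of 4.7e-06 (adjusted p = 0.88 with an estimated correlation). Complement C3 had 1.06 ± 0.42 and Lgals3 0.75 ± 0.35 (adjusted p = 0.82 and 0.88). In 4sU mice 4336 genes were higher and 4761 lower, and averaged over both arms 3429 were higher and 3621 lower.

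This difference between the arms went with a division of the libraries that was also present without chronic stress. In the 10 baseline and acute 4sU libraries 16.1% to 17.4% of reads lay in annotated 3′ UTR intervals, against 18.2% to 23.9% in the other 16 libraries. Their mean log2 CPM over 18 oligodendrocyte and myelin markers was 7.42 to 7.96, against 8.27 to 9.30. Chronic against baseline 4sU mice, and the average over both arms, cross this division. Chronic against baseline DMSO mice, and chronic 4sU against chronic DMSO mice, lie on 1 side of it.

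**Figure D2:**
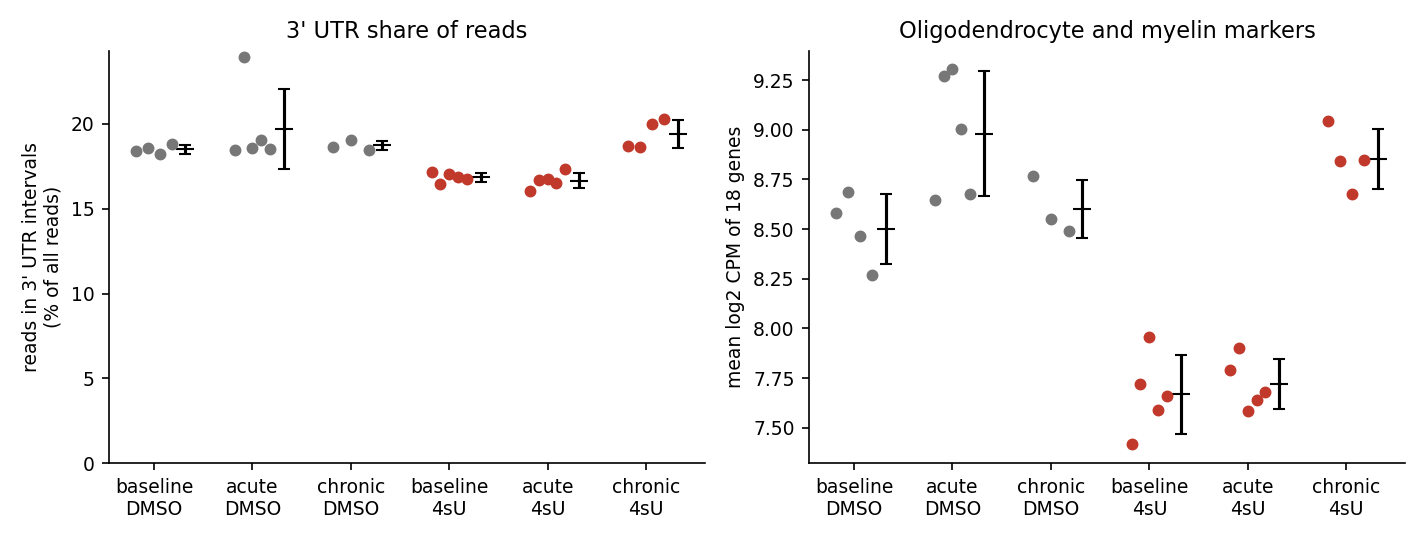
Share of reads in 3′ UTR intervals (%) and mean log2 CPM of 18 oligodendrocyte and myelin markers in each amygdala library, with points for libraries, black dashes and bars for the group mean ± SD, grey for DMSO and red for 4sU. The 10 baseline and acute 4sU libraries lie at 16.1% to 17.4% and 7.42 to 7.96, below the other 16 libraries on both measures.

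In the average over both arms, 15 of the 18 oligodendrocyte and myelin markers rose and 0 fell (median 0.70, list adjusted p = 1.9e-15; adjusted p = 0.40 with an estimated correlation). Tspan2 was at 1.01 ± 0.06, Mal at 0.88 ± 0.07 and Mobp at 0.73 ± 0.07 (adjusted p = 1.6e-09, 9.2e-08 and 3.4e-07). Of 18 endothelial and pericyte markers 9 rose, such as Slco1a4 (0.72 ± 0.05, adjusted p = 1.5e-08) and Rgs5 (0.58 ± 0.06, adjusted p = 4.6e-07), with a list adjusted p of 0.0043 (adjusted p = 0.405 with an estimated correlation). Of 24 postsynaptic genes 3 rose and 11 fell, with the NMDA receptor subunit Grin1 at -0.52 ± 0.05 (adjusted p = 2.2e-07). Of 30 immediate early genes 0 rose and 9 fell, among them Egr4 (-0.90 ± 0.14, adjusted p = 9.8e-05) and Fosb (-0.51 ± 0.10, adjusted p = 0.00060). The last 2 lists each had adjusted p = 0.045 (adjusted p = 0.98 with an estimated correlation). The 4 Y-linked genes rose as well, Ddx3y by 0.62 ± 0.06 (adjusted p = 1.3e-07; list adjusted p = 0.00014; adjusted p = 0.089 with an estimated correlation). Myelin, endothelial, immediate early and Y-linked genes also had called members between 4sU and DMSO mice at baseline, which lie on the 2 sides of the division.

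The largest named rises of the average were those of Pmch (3.73 ± 0.93, adjusted p = 0.0055), which ranged from 9.14 to 87.9 CPM in chronic 4sU libraries, and the homeobox genes Lhx1 (2.36 ± 0.29, adjusted p = 3.8e-06) and Lmx1b (1.74, adjusted p = 0.00017). For Pmch, chronic stress versus baseline, expression without chronic DMSO library 1, gave 2.91 (adjusted p = 0.17). Its call was also lost with 3′ UTR reads, without the 5 libraries low in glutamatergic markers and with a term for the division. The nicotinic receptor subunit Chrnb3 (1.52, adjusted p = 0.00097) and the RNA-binding Lsm5 (1.45, adjusted p = 0.00011) followed, with the small nucleolar RNAs Snord64 (1.70) and Snora28 (1.10), which lie in host transcripts and may share their reads. Falls were led by Dkkl1 (-1.88 ± 0.35), Pappa2 (-1.49 ± 0.21), Glipr1 (-1.32), Lrg1 (-1.30), the neuronal pentraxin receptor Nptxr (-1.28), neuropeptide S receptor Npsr1 (-1.25), Tfap2d (-1.25) and Mei1 (-1.22). Named rises and falls were chosen to have the same sign in both arms, and in DMSO mice none passed by edgeR. Lhx1 had 1.52 (adjusted p = 0.55), Pappa2 -1.55 (adjusted p = 0.40) and Nptxr -0.18 (adjusted p = 0.97). Of the 12 genes fixed beforehand, Tsc22d3 (0.44, adjusted p = 0.00048), Nr3c1 (0.14, adjusted p = 0.028) and Egr1 (-0.55, adjusted p = 0.027) passed in the average. Egr1 lost its call in 6 and Nr3c1 in 2 of 16 fits without 1 library. Both calls were also lost with the replicate block, with 3′ UTR reads and without the 5 libraries low in glutamatergic markers. Egr1 lost its call with a term for the division too, and Nr3c1 with all 6 groups in a fit. In DMSO mice Tsc22d3 had -0.04, Nr3c1 -0.14 and Egr1 -0.35 (adjusted p = 0.98, 0.88 and 0.93), and Nr3c1 had 0.41 in 4sU mice (adjusted p = 2.2e-05; difference between arms 0.55, adjusted p = 0.00021).

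The test of the difference between arms called 2917 genes higher and 3204 lower, with Mal at 1.76 (adjusted p = 2.9e-07) and Tsc22d3 at 0.97 (adjusted p = 0.00032). Of 18 oligodendrocyte markers 14 were higher (adjusted p = 1.2e-14; adjusted p = 0.30 with an estimated correlation). When the division of libraries was added as a term to the fit of the average, a choice made after the data were seen, 0 genes passed by edgeR (377 at an unadjusted p under 0.05).

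Among chronically stressed mice, 4sU was compared with DMSO to ask what the label itself changed. The proliferation marker Mki67 was lower with 4sU, 2.37 against 6.08 CPM (log2 fold change -1.37 ± 0.26, adjusted p = 0.047) and topoisomerase Top2a 1.26 against 6.28 CPM (-2.32 ± 0.32, adjusted p = 0.0065). The replication helicase subunit Mcm3 was 4.23 against 10.1 CPM (-1.26 ± 0.20, adjusted p = 0.020) and the mitotic kinase Pbk had -2.57 ± 0.45 (adjusted p = 0.033). Pclaf (-1.91), Uhrf1 (-1.64), the macrophage lectin Siglec1 (-1.54) and the defensin Defb11 (-1.94) were lower too, at adjusted p = 0.047, 0.026, 0.047 and 0.033. Tspan2 and Gpr17 of the myelinating lineage were higher, Tspan2 at 475 against 324 CPM (0.54 ± 0.09, adjusted p = 0.020) and Gpr17, a receptor of newly forming oligodendrocytes, at 99.5 against 62.0 CPM (0.67 ± 0.09, adjusted p = 0.0070). So were Sspo (0.77 ± 0.15) and Plekha1 (0.29 ± 0.06, adjusted p = 0.047 for each). In all, 4 genes were higher and 18 lower, with 4 libraries against 3. Top2a alone among these 12 named genes kept its call in each of the 7 fits without 1 library, while Mki67 lost it in 6. With only these 2 groups in a fit all 12 lost their calls, Top2a included. Of 35 splits of these 7 libraries, the real one counted, 3 called as many genes, and another split called 1933, so chance was not excluded.

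All 24 interferon-stimulated genes (median -0.74, list adjusted p = 5.3e-20) and all 21 reactive glia and injury genes (median -0.60, adjusted p = 6.1e-17) had lower values with 4sU (adjusted p = 0.12 for both lists with an estimated correlation). Of these, 15 and 14 were lower when adjusted over the list alone and none over all genes by edgeR. Examples are Bst2, which tethers virions (-1.65 ± 0.40, adjusted p = 0.13), and the protease inhibitor Timp1 (-2.07 ± 0.54, adjusted p = 0.18). All 16 choroid plexus and ependymal markers were lower in value (median -0.83, list adjusted p = 5.4e-14; adjusted p = 0.18 with an estimated correlation), and 3 of 16 microglia markers when adjusted over the list alone (median -0.28, adjusted p = 8.6e-07; adjusted p = 0.24 with an estimated correlation). Oligodendrocyte markers had 1 riser over all genes and 8 over the list alone (median 0.32, adjusted p = 5.9e-13; adjusted p = 0.185 with an estimated correlation). Precursor markers had 1 and 3 (median 0.20, adjusted p = 1.15e-08; adjusted p = 0.12 with an estimated correlation). Hypothalamic markers leaned upward (adjusted p = 3.9e-06; adjusted p = 0.12 with an estimated correlation) with the orexin precursor Hcrt at 6.11 ± 1.15 and Pmch at 5.17 ± 0.98 (adjusted p = 0.055 and 0.063). Chronic 4sU library 3 had a mean log2 CPM of 2.54 over the choroid markers, against 4.44 to 4.79 in the other 3 libraries of its group. Over the reactive glia genes it had 2.032, against 2.613 to 2.677. Chronic 4sU library 1 had 6.016 over the precursor markers, against 5.882 to 5.884 in the others of the group. The count of 22 genes became 7 without chronic 4sU library 1 or library 3, 12, 2 and 11 without chronic DMSO library 1, 2 or 3, and 147 by DESeq2.

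At baseline and under acute stress the same comparison crosses the division of libraries. At baseline 3378 genes were higher and 3316 lower with 4sU, and under acute stress 3756 and 3969. Oligodendrocyte markers had 14 of 18 lower at baseline (median -0.82, list adjusted p = 1.6e-08; adjusted p = 0.98 with an estimated correlation) and 16 under acute stress (median -1.42, adjusted p = 8.3e-18; adjusted p = 0.24 with an estimated correlation), with Mal at -1.21 and -1.77 (adjusted p = 6.3e-07 and 4.8e-09). Endothelial markers had 10 of 18 lower at baseline (adjusted p = 0.0091; adjusted p = 0.98 with an estimated correlation). Presynaptic genes had 13 of 24 higher at baseline (median 0.33, adjusted p = 0.0041; adjusted p = 0.98 with an estimated correlation). Immediate early genes had 12 of 30 higher in both states, with 1 lower at baseline (adjusted p = 0.12) and 0 under acute stress (adjusted p = 0.012; adjusted p = 0.83 with an estimated correlation). All 4 Y-linked genes were lower at baseline, Ddx3y by -1.10 (adjusted p = 1.6e-07), with a list adjusted p of 0.00015 (adjusted p = 0.032 with an estimated correlation). At baseline the named genes with the largest rises were Erdr1 (2.84 ± 1.06, adjusted p = 0.038, lost in 7 of 9 fits without 1 library, a pseudoautosomal gene whose reads are shared between X and Y), the hippocampal Fibcd1 (2.76, 130 against 19.3 CPM) and Nptxr (1.97). The largest falls were those of the dopamine transporter Slc6a3 (-3.13, adjusted p = 0.0055), Snord64 (-2.28) and Ccdc152 (-2.28, adjusted p = 3.5e-05), which overlaps Selenop on the opposite strand, so that the reads of the pair may be mixed. Under acute stress they were Tfap2d (3.04), Nptxr (2.77), vasopressin precursor Avp (2.24), Lsm5 (-3.46, adjusted p = 4.3e-06) and Lhx1 (-2.68).

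Chronic and acute stress were then set against each other, averaged over the arms. Glucocorticoid-responsive genes were lower after chronic than after acute stress, 23 of 26 with 0 higher (median -0.80, list adjusted p = 4.0e-16; adjusted p = 0.092 with an estimated correlation). Fkbp5 was lower by -0.95 ± 0.11 (adjusted p = 1.2e-06), Sgk1 by -1.22 ± 0.24 (adjusted p = 0.00037), Ddit4 by -1.45 (adjusted p = 2.3e-08) and Nfkbia by -1.28 (adjusted p = 6.5e-08), while Nr3c1 was higher (0.34, adjusted p = 0.0012). In 4sU mice the comparison crosses the division of libraries, and Nr3c1 went from 67.0 ± 5.1 CPM (acute) to 101 ± 4.9 CPM (chronic). In DMSO mice it went from 92.8 ± 18 to 98.8 ± 8.9 CPM. Over all genes 2742 were higher and 2779 lower of 16310 tested, and 165 passed (52 higher and 113 lower) with the division of libraries as a term. In that fit the chronic side rests on chronic DMSO libraries alone. Of the genes called against baseline in both states, 85 were higher in both, 62 lower in both and 38 went opposite ways. Independent lists would share 49.9 and 33.2, and simulated unchanged groups called too few genes to share any. In 4sU mice 11 higher and 3 lower were shared, where independent lists would share 8.92 and 2.99, and in DMSO mice 0, since no gene passed there under chronic stress by edgeR. With the baseline libraries split between the comparisons, 13 higher and 3 lower, or 5 and 3, were shared, where independent lists would share 11.6 and 3.45, or 3.57 and 0.891. Across 15933 genes, which are not independent replicates, the log2 fold changes had a covariance of 0.0206, against 0.0122 in simulated unchanged groups. In the simulation both comparisons also shared simulated baseline libraries, but each gene had 1 mean in all groups. It holds no division of libraries, which the chronic average crosses, so the covariances do not separate a shared response from that division. The correlation of the log2 fold changes was 0.317 against a simulated 0.488, and 58.2% of genes had the same sign against a simulated 65.9%. The covariance was 0.0235 against a simulated 0.0265 in DMSO mice and 0.0244 against 0.0214 in 4sU mice.

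Metabolic labelling was measured as the percentage of covered T positions read as C in 3′ UTRs. It was 0.0478% ± 0.0050 in baseline 4sU (n = 5) against 0.0275% ± 0.0030 in baseline DMSO libraries (n = 4), 0.0497% ± 0.0082 (n = 5) against 0.0242% ± 0.0018 (n = 5) under acute stress, and 0.0627% ± 0.0135 (n = 4) against 0.0250% ± 0.0014 (n = 3) under chronic stress. The excess was 0.0203, 0.0255 and 0.0376 percentage points, and the 4sU rate was 1.74, 2.06 and 2.5 times the DMSO rate. The first 2 of these comparisons cross the division of libraries, and only the chronic one lies on 1 side. No DMSO library lies on the side of the baseline and acute 4sU libraries, so the background rate there is unknown. The median rate over genes had a smaller excess of 0.00293, 0.00643 and 0.0114 percentage points, which passed under acute and chronic stress and not at baseline (exact permutation p = 0.0159, 0.0286 and 0.127). For the overall rate, each p was the smallest its design allows in a two-sided exact permutation test, 0.00794 at baseline and under acute stress and 0.0286 under chronic stress. Reads with a conversion made up 1.48% of reads in baseline 4sU libraries against 1.02% in DMSO libraries. Among 4sU mice the overall rate was not shown to differ from baseline under acute stress (exact permutation p = 0.690) or chronic stress (exact permutation p = 0.0556). Without any 1 of the 7 chronic libraries, 4sU against DMSO had the smallest exact p then possible, 0.0667 or 0.10.

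**Figure D3:**
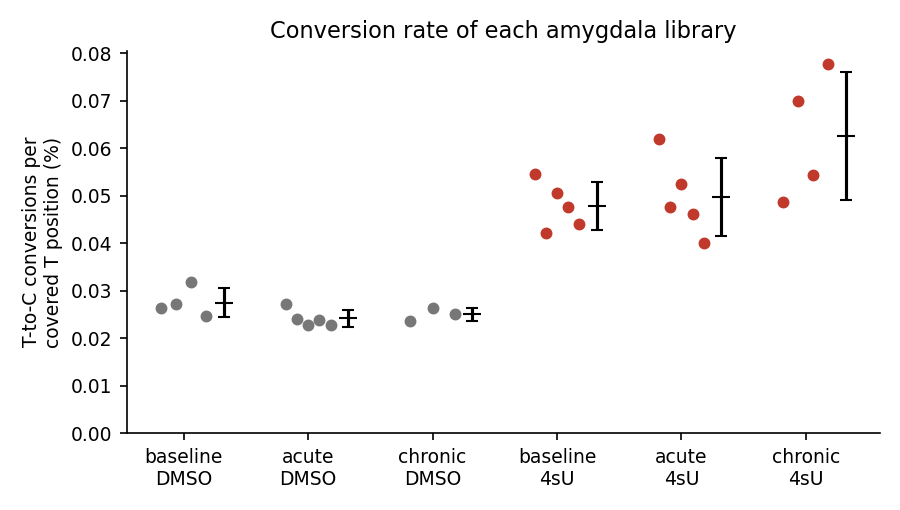
T-to-C conversion rate (% of covered T positions in 3′ UTRs) in each amygdala library, with points for libraries, black dashes and bars for the group mean ± SD, grey for DMSO and red for 4sU. The 4sU means are 0.0478%, 0.0497% and 0.0627% at baseline, under acute and under chronic stress, and the DMSO means 0.0275%, 0.0242% and 0.0250%. Baseline and acute 4sU libraries lie across the division of libraries from all DMSO libraries.

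The 10 labelled genes with the largest excess over DMSO at baseline included glial and lipid enzyme genes. At baseline the fatty acid desaturase Scd1 (3′ UTR at chromosome 19, 44394450 to 44397917) had 0.237% against 0.0266% (log2 ratio 3.15, adjusted p = 1.3e-38) and the astrocyte filament gene Gfap (chromosome 11, 102887336 to 102888675) 0.196% ± 0.042 against 0.0259% (2.92, adjusted p = 3.2e-36). The microglial Fc receptor chain Fcer1g had 0.431% ± 0.30 against 0.0441% and the lysosomal protease Ctss 0.331% ± 0.32 against 0.0288%, at means of 1759 and 1917 covered T positions in baseline 4sU libraries. Both calls were lost with limma, and that of Ctss also with the replicate block and without baseline 4sU library 5 (log2 ratio 2.86, adjusted p = 0.064). Apolipoprotein D (Apod) had 0.254% against 0.0436%, the astrocyte acyl-CoA synthetase Acsbg1 0.202% against 0.0294%, and the class I gene H2-D1, whose reads are shared with close paralogs, 0.228% against 0.0376%. Trnt1 (0.529% against 0.232%) and Lamp3 (0.336% against 0.0925%) had a high DMSO background. Under chronic stress, where both groups lie on 1 side of the division of libraries, Trnt1 had no excess (0.249% against 0.274%). Lamp3 had 0.0967% against 0.0641% there. Lhx8 (0.339% ± 0.67) varied widely between libraries and lost its call without baseline 4sU library 4 (log2 ratio 1.73, adjusted p = 0.71). Of 8484 genes tested, 618 were above and 14 below the DMSO rate at baseline, 997 and 12 of 8675 under acute stress, and 1175 and 9 of 8748 under chronic stress. With limma on the rates the totals were 143, 458 and 0. At baseline and under acute stress 4sU and DMSO libraries lie on the 2 sides of the division of libraries, and under chronic stress on 1 side.

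Lists were ranked by their median baseline excess among random lists of the same size and expression. Astrocyte markers (15 genes, median 0.0629 percentage points) and reactive glia genes (8 genes, 0.133) lay at percentile 100, and presynaptic genes (24 genes, 0.0409) at 99.4. Endothelial markers (12 genes, -0.0114) and striatal neuron markers (14 genes, -0.00275) lay at 1.29 and 1.13. The other lists lay between these percentiles, among them glucocorticoid-responsive genes at 13.5 and immediate early genes at 78.0. Microglia markers (10 genes, -0.00241) lay at 18.55, although Ctss is a member. Oligodendrocyte markers lay at 9.93, although Mbp, an abundant myelin transcript, had an excess of 0.106.

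Stress was then tested on the conversion rate per gene in 4sU mice. For acute stress 0 of 8294 genes passed by edgeR (441 at an unadjusted p under 0.05, 0 by limma, and 1 when reads with a conversion were tested). In simulated data this test recovered 0% of genes changed 1.5-fold and 11.9% changed 2-fold, and the chronic test 0% and 1.5%. The simulated spread was set and not estimated from these libraries. A count of 0 therefore does not show that labelling was unchanged. Fkbp5, Sgk1 and Tsc22d3, which rose in level, had acute log2 rate ratios of 0.21, 0.21 and 0.20 (adjusted p = 0.996 for each). None was labelled above the DMSO background by edgeR, with Sgk1 at 0.0240% against 0.0227% under acute stress. For chronic stress 9 genes rose and 11 fell of 8492. Myelin transcripts were among the risers. Cldn11 went from 0.0401% to 0.138% (1.36 ± 0.23, adjusted p = 2.5e-05), Cnp from 0.0285% to 0.0859% (1.11, adjusted p = 0.0034) and Mal from 0.106% to 0.237% (0.77 ± 0.15, adjusted p = 0.00039). Others were Tmem47 (0.85), Atp6v1h (2.92), Bbip1 (2.88), Mbd3 (2.28) and Lars2 (2.27). Lrrc58 went from 0.138% to 0.0698% (-1.40 ± 0.18, adjusted p = 2.2e-10), Trnt1 from 0.529% to 0.249% (-1.46, adjusted p = 0.00059) and Dpy19l1 from 0.209% to 0.102% (-1.42). In DMSO mice the baseline and chronic rates were 0.0390% and 0.0319% for Lrrc58, 0.232% and 0.274% for Trnt1, and 0.0828% and 0.0869% for Dpy19l1. Lhx8 (-4.35), Csrnp2 (-3.26), Ythdc2 (-2.69), Lamp3 (-2.17) and Prpf4b (-1.70) were lower too. Cldn11, Mal, Lrrc58, Trnt1 and Dpy19l1 kept their calls in all 9 fits without 1 library. With no rescaling of libraries to a common overall rate, 21 genes rose and 1 fell, and all named fallers but Csrnp2 lost their calls. This comparison crosses the division of libraries as well. The count became 8, 12 and 11 without chronic 4sU library 2, 3 or 4, 11 in the test of the difference from DMSO mice, and 0 by limma.

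In auditory cortex, 4sU was compared with no 4sU in 3 libraries each, and 0 of 20358 transcripts passed by edgeR (717 at an unadjusted p under 0.05, 8 by DESeq2). Among the transcripts with the smallest unadjusted p-values were glial and macrophage genes. The acute-phase gene Serpina3n was 185 ± 50 against 89.1 ± 13 CPM (log2 fold change 1.05 ± 0.20) and Gfap 994 ± 166 against 554 ± 94 CPM (0.84). The macrophage gene Ms4a6d was 4.49 against 0.705 CPM (2.65 ± 0.45) and Ly86 44.7 against 20.8 CPM (1.11), and all 4 had adjusted p = 0.293. Of 12 measured reactive glia and injury transcripts 9 lay above 0 and 5 were higher when adjusted over the list alone (median 0.74, list adjusted p = 2.3e-07; adjusted p = 0.91 with an estimated correlation). Microglia markers leaned upward (6 of 7, list adjusted p = 0.010) and oxidative phosphorylation genes downward (13 of 45 above 0, median -0.20, adjusted p = 0.010), both with adjusted p = 0.91 with an estimated correlation. Actb averaged 5.7 counts per cortex library against 20428.8 in amygdala, while Snap25 had 34428.5 against 24608.5, so levels were not compared between the tables. With no filter on low counts 38 transcripts passed, and 2, 3 or 6 when 1 library was left out.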

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

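Of the tests here, those of gene length and of a single wrong label were chosen before their results were seen, and all others after.

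The effect of chronic stress differed between the injection arms: the test of the difference called 6121 genes, and 4sU and DMSO mice differed in 6694 genes at baseline, 7725 under acute stress and 22 under chronic stress. For the genes called at baseline as a set, an effect of 4sU that acts in every state is argued against. The slope of the chronic on the baseline 4sU effect over them was 0.0175 (SE 0.00376). Single genes are not covered by this. Top2a, lower with 4sU under chronic stress, had 1.22 to 2.85 CPM with 4sU against 2.95 to 5.75 with DMSO at baseline. Under acute stress it had 1.28 to 2.22 against 3.80 to 8.52 CPM. Gene length explained 1.28% of the variance of the baseline effect, which argues against a length bias. A difference between sets of libraries remains a candidate explanation: the acute 4sU effect followed the difference between baseline and chronic 4sU libraries, which share no library with it, with a slope of 0.843 (SE 0.00384). An effect of 4sU lost under chronic stress would give that slope too, and the labels name no batch, so this stays open.

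Baseline DMSO library 4 had a glucocorticoid list score (mean log2 CPM) of 5.25, where the other baseline DMSO libraries reached 4.76 and the acute DMSO libraries started at 5.24 and averaged 5.51, so its score lay within the acute range. A swap with an acute DMSO library is argued against, since the lowest of those lay above the other baseline libraries by 0.487, more than their SD of 0.249. A single wrong label is argued against by the slope of this library on the acute response of 4sU mice, 0.547 (SE 0.0563), where single acute DMSO libraries had 0.961 to 1.28, although the other baseline DMSO libraries had at most 0.153. No biological explanation was tested. This library also stood away from the other 3 of its group in interferon-stimulated genes (3.458 against 2.551 to 2.59) and striatal markers (7.442 against 6.742 to 6.815).

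The 5 libraries low in glutamatergic markers raise the question of a lower share of neurons. Their GABAergic scores of 6.05 to 6.17 lay around the median of 6.06, a fall of -0.0208 relative to the glutamatergic one. This argues against a fall shared by both lists of neuron markers. More striatal tissue could keep GABAergic scores up, so the test does not decide on the share of neurons. Such tissue in the dissection may account for part of the low glutamatergic scores, as 4 of the 5 libraries had striatal scores above the median. The other did not, and this test does not decide either. A fall that acute stress causes in every mouse is argued against. Acute 4sU libraries had glutamatergic scores of 4.80 to 5.34, against 4.78 to 5.21 in baseline 4sU libraries, and acute DMSO libraries 2 and 5 had 4.91 and 5.06. An effect of stress in some mice stays open, untested, since 3 of the 5 libraries are acute DMSO mice.

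Single libraries stood far from the rest of their group in 19 of 205 tests of a group, where chance gives about 10.2. Acute DMSO library 2 had 23.92% of reads in 3′ UTR intervals (others 18.45 to 19.03), and mean log2 CPM of 7.878 over ribosomal protein genes (6.897 to 7.088), 7.588 over oxidative phosphorylation genes (6.632 to 6.758) and 4.24 over regulators with short-lived mRNA (3.793 to 3.906). Chronic 4sU library 3 was low in heat shock genes (5.597 against 5.697 to 5.717), reactive glia genes (2.032 against 2.613 to 2.677), endothelial markers (4.696 against 4.795 to 4.805) and choroid markers (2.541 against 4.44 to 4.785). Chronic 4sU library 1 was high in oligodendrocyte precursor markers (6.016 against 5.882 to 5.884) and blood genes (2.577 against 1.62 to 1.745). Baseline 4sU library 1 was low in precursor markers (5.799 against 5.933 to 5.979), library 3 in presynaptic genes (8.812 against 8.98 to 9.024) and library 5 in oxidative phosphorylation genes (6.539 against 6.725 to 6.753). Baseline DMSO library 3 was high in glutamatergic markers (4.671 against 4.27 to 4.32) and low in log2 CPM of Arc (5.382 against 5.751 to 5.812). Egr1 was high in acute 4sU library 4 (7.543 against 6.773 to 6.986), and Crh low in acute DMSO library 3 (2.605 against 3.014 to 3.143).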

How the results depend on the processing

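Fits with a term for the library sets, fits without the 5 libraries low in glutamatergic markers and cortex counts per symbol were chosen after the results were seen. Where a value below differs from the reported one and nothing else is said, the cause was not tested.

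With DESeq2 the counts were 667 (acute average), 96 (acute, 4sU mice), 819 (acute, DMSO mice), 20 (acute difference between arms), 11 (chronic, DMSO mice), 147 (4sU against DMSO under chronic stress) and 8 (cortex). With 3′ UTR reads they were 186 for the acute average, 149 for acute DMSO mice and 5 for 4sU against DMSO under chronic stress. In 1 fit of all 6 groups, acute 4sU mice gave 67 genes and 4sU against DMSO under chronic stress 8. With only the 2 groups compared in a fit, the spread comes from fewer samples, and from those 2 groups alone. Acute 4sU mice then gave 137, acute DMSO mice 4 and 4sU against DMSO under chronic stress 0 genes by edgeR. Pairs of acute DMSO libraries had a chi-square per degree of freedom of 12.3 to 113, and pairs of acute 4sU libraries 5.56 to 16.7. With no filter the cortex gave 38. Without the 5 libraries low in glutamatergic markers the acute average gave 1112 genes (308 of the 382 among them), acute DMSO mice 2391 (291 of the 402), the acute difference between arms 313 and chronic DMSO mice 3. Of the acute DMSO group these fits keep libraries 2 and 5 alone. With a term for the library sets the chronic average gave 0 genes by edgeR and chronic against acute stress 165. That term takes up the contrast between baseline and chronic 4sU mice, so the chronic side of these fits rests on chronic DMSO libraries alone.

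For conversion, limma on the rates called 143, 458 and 0 labelled genes and 0 genes under chronic stress. Reads with a conversion gave 1 gene under acute stress, and the test against DMSO mice 11 under chronic stress. The median rate over genes had an excess of 0.00293 percentage points at baseline and lost its call (exact permutation p = 0.127). Camera made 8 calls with an estimated correlation. With the baseline libraries split, 16 or 8 genes were shared by the acute and chronic responses in place of 147.

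Replicate numbers did not pair the samples: over 16 pairs of groups the correlations of same-numbered libraries ran from -0.425 to 0.355, and in 0 of the 16 were all above 0.1. The replicate block gave 11 genes for 4sU against DMSO under chronic stress and 9 for conversion under chronic stress, and moved no other count of calls by over 1.5 times.

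Leaving out 1 library gave these ranges. The acute average ran from 249 (without baseline DMSO 1; 253 without baseline DMSO 2) to 787 (without acute DMSO 2). Acute 4sU mice ran from 25 (without baseline 4sU 5; 27 without 2) to 42. Acute DMSO mice ran from 143 to 906, with 143, 175 and 169 without baseline DMSO 1, 2 and 3, and 666, 906, 248, 200 and 716 without acute DMSO 1 to 5. The acute difference between arms ran from 0 to 12 (1, 4 and 12 without acute DMSO 2, 4 and 5) and chronic DMSO mice from 0 to 1 (1 without baseline DMSO 3 or chronic DMSO 3). 4sU against DMSO ran from 5808 to 6313 at baseline, 7106 to 9008 under acute stress and 2 to 19 under chronic stress (7, 7, 12, 2 and 11 without chronic 4sU 1 and 3 and chronic DMSO 1, 2 and 3). The chronic average ran from 6470 to 7172, chronic 4sU mice from 8593 to 8858, the chronic difference between arms from 5229 to 6069 and chronic against acute stress from 4705 to 6695. The cortex ran from 0 to 6 (2 and 3 without 4sU 2 and 3, 6 without no-4sU 1). Labelled genes ran from 522 to 652, 858 to 1058 and 891 to 1279. Conversion ran from 0 to 1 under acute stress (1 without baseline 4sU 1 or 4) and 8 to 22 under chronic stress (8, 12 and 11 without chronic 4sU 2, 3 and 4). The overall excess ran from 0.0186 to 0.0218, 0.0224 to 0.0279 and 0.0326 to 0.0423 points, the last with an exact p of 0.0667 or 0.10 since fewer samples allow no smaller one. Lists outside the central range of random lists ran from 5 to 7.

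Of 2740 alternative values of named genes, over 145 pairs of a gene and a comparison, 2393 kept their side of the threshold, 333 lost their call, 8 gained one and 6 changed sign. Glipr1 became 0.13 (chronic average, 3′ UTR reads). With the term for the library sets, where chronic 4sU libraries do not inform the chronic effect, Nptxr became 0.053, Tsc22d3 -0.087 and Nr3c1 -0.12. The log2 ratio of Ythdc2, chronic stress versus baseline, conversion rate, became 0.11 with the replicate block, and ran from -3.04 to 0.13 with 1 library left out (0.13 without baseline 4sU 5). In the cortex the depth and spread of 3 against 3 libraries recovered 0% of simulated 1.5-fold changes, so such changes were not detectable there.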

Other observations

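Of the tests here, the splits of the acute average, of the acute arms and of their difference were chosen after the results were seen, and the other splits before. Genes of the fit without 5 libraries were also chosen after the data were seen.

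Further genes of the acute response were picked from the fit without the 5 libraries low in glutamatergic markers, and passed over all libraries too by edgeR. Over all libraries the ubiquitin ligase adaptor Spsb1 had a log2 fold change of 0.81 (adjusted p = 3.9e-06), the GTPase Rhou 0.81 (adjusted p = 2.6e-05) and the EGF receptor inhibitor Errfi1 1.00 (adjusted p = 9.0e-06). The metabolic transcription factor Klf15 had 0.66 (adjusted p = 1.3e-05), the redox and glucose uptake regulator Txnip 0.88 (adjusted p = 0.00019) and the leukocyte phosphatase Ptprc -0.77 (adjusted p = 0.00032). Without the 5 libraries their values were 0.84, 0.81, 1.00, 0.67, 0.99 and -0.99. In chronically stressed DMSO mice, where no gene passed by edgeR, 14 of 19 circadian clock genes had negative log2 fold changes (median -0.12, list adjusted p = 0.00075; adjusted p = 0.88 with an estimated correlation), with Dbp at -0.51 ± 0.19 and Nr1d1 at -0.20 ± 0.07 (adjusted p = 0.80 for each). All 15 striatal markers had negative values (median -0.31, list adjusted p = 0.034; adjusted p = 0.88 with an estimated correlation). Baseline DMSO library 4 had a mean log2 CPM of 7.442 over the striatal list, against 6.742 to 6.815 in the other 3 libraries of its group. In the same mice 38 of 43 ribosomal protein genes lay above 0 (median 0.07, list adjusted p = 5.3e-05; adjusted p = 0.88 with an estimated correlation).

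Some labelled genes outside the baseline selection had a large excess over DMSO in stressed mice. Under acute stress the secreted glycoprotein Spp1 had 0.510% ± 0.65 of T positions converted against 0.0204% in DMSO mice (log2 ratio 4.32 ± 0.76, adjusted p = 3.4e-07), at a mean of 1422 covered positions, and lost its call with limma. The selenium carrier Selenop had 0.140% against 0.0209% (2.76 ± 0.26, adjusted p = 2.9e-24) and the membrane proteolipid Gpm6b 0.200% against 0.0342% (2.55 ± 0.18, adjusted p = 1.5e-42). Under chronic stress the retinaldehyde dehydrogenase Aldh1a1 had 0.104% against 0.00424% (4.26 ± 1.07, adjusted p = 0.00089) and the tetraspanin Tspan6 0.195% against 0.0127% (3.71 ± 0.95, adjusted p = 0.0012), and both calls were lost with limma. The rates in baseline 4sU mice were 0.192% for Spp1, which did not pass there (adjusted p = 0.16), 0.179% for Selenop, 0.186% for Gpm6b, 0.174% for Aldh1a1 and 0.195% for Tspan6.

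Other splits of the same libraries into groups of the same sizes were fitted in the same way, the real split counted. A share of splits under 0.05, not adjusted over the comparisons, was taken to speak against chance without excluding it. The acute average had such a share, as 2 of 100 splits gave as many genes, although another split called 466 against the real 382. So did acute 4sU mice (1 of 100, real 43, highest other 0). Acute DMSO mice did not (5 of 100, real 402, highest other 703). Where the real count was 0, every split gives as many and the splits test nothing, as for the acute difference between arms (100 of 100; highest other 8), chronic DMSO mice (35 of 35; highest other 1) and conversion under acute stress (100 of 100; highest other 5). The share was under 0.05 for the chronic average (1 of 100, real 7050, highest other 2365) and chronic 4sU mice (1 of 100, real 9097, highest other 6396). It was also under 0.05 for the chronic difference between arms (1 of 100, real 6121, highest other 2220). Chronic against acute stress had 2 of 100, although another split called 6185 against the real 5521. The same held for 4sU against DMSO at baseline (1 of 100; 6694, highest other 4335) and under acute stress (1 of 100; 7725, highest other 4207). For these 6 the division of libraries follows the groups, so a share under 0.05 does not separate stress or 4sU from it. Under chronic stress 3 of 35 splits gave as many genes as 4sU against DMSO (22), so chance was not excluded, and the highest other called 1933 genes, which points to a structure of these 7 libraries other than the injection. For labelled genes the share was under 0.05 at baseline (1 of 100, real 632, highest other 472) and under acute stress (1 of 100, real 1009, highest other 438). The same was seen for labelled genes under chronic stress (1 of 35, real 1184, highest other 793) and conversion under chronic stress (1 of 100, real 20, highest other 15). Apart from labelling under chronic stress, these comparisons also follow the division of libraries. The cortex allows 10 splits, too few for a share under 0.05; 10 of 10 gave as many as the real 0, as they must, and the highest other gave 5.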
